A study of Danio rerio with 9 samples.

How the data were processed

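The series measured RNA in whole zebrafish larvae (Danio rerio) at 8 days post fertilization. It holds 9 libraries, 3 for each of 3 genotypes. The wild-type libraries carry the name of the AB standard line in the file headers. The single mutants were homozygous for the stl700 allele of fam177a1a, and the double mutants were homozygous for stl700 and for the stl746 allele of fam177a1b. Per the labels' protocols, each library was made from total RNA pooled from 7 larvae, with ribosomal RNA depleted before sequencing in pairs on a NovaSeq instrument. The labels do not say whether the 3 libraries of a genotype came from different clutches or days, nor at what hour the larvae were collected.

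The deposited table holds 1 row per gene name, 28802 in all, with a length in bases and a value for each library. The deposited values are raw counts: each is a whole number, and each library has its own total. Per the submitters' processing notes, cutadapt, STAR, featureCounts and DESeq2 were used with the build GRCz11. No versions are given there. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Genes that share a name appear to have been added together, since the row named 5S_rRNA has a length of 224739 bases. Per the file headers, all 9 sample columns matched a label, and none was left unused.

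The reference used for names belongs to another assembly, GRCz12tu, so no coordinates or chromosome numbers are given. It supplied older symbols, the chromosome on which each gene lies and which genes neighbour each other. No row of the deposited table is named fam177a1a or fam177a1b. The row named fam177a1 was taken as the targeted gene by its symbol. The names used here list FAM177A1 under more than 1 identifier, so whether that row holds counts of 1 or of both zebrafish genes is not recorded, and fam177a1b was not analysed here as a gene of its own.

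From the counts, genes were kept with edgeR's filterByExpr by genotype, which left 21694 genes. Libraries were scaled with TMM factors, and log2 fold changes were tested with edgeR's quasi-likelihood F test with robust estimation of the spread. All 9 libraries entered 1 fit with genotype as the only factor, which leaves 6 residual degrees of freedom. Each of the 3 comparisons was adjusted by the Benjamini-Hochberg method over all tested genes, and a gene was called at an adjusted p under 0.05. CPM values rest on TMM-scaled totals and are means over the 3 libraries of a genotype with the SD. The common biological coefficient of variation was 11.4%. For a genotype without a count, folds are lower bounds computed against 3 counts over its 3 libraries. For genes with 1 to 3 counts in a genotype, the ratio of the counts summed over a genotype's libraries, scaled to their summed totals, is given with its exact 95% counting interval. Such intervals and bounds cover counting error only.

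The genotypes, the comparisons, the tests, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The 46 gene lists cover the Golgi and secretion, stress, immunity, cell division, metabolism, and the tissues and cell types of a larva, and 4 of them were defined by name patterns. Of 2194 distinct symbols written into the others, 2037 were in the deposited table, and some genes stand in more than 1 list. Counts of called list members stand beside a share called over all genes of 42.0% in single mutants against wild type. That share was 32.2% in double mutants against wild type and 1.67% between the mutants. Lists were tested with limma's camera on voom log2 CPM with its preset correlation of 0.01, two-sided, and adjusted over the 46 lists within each comparison. Each test was repeated with the correlation estimated from the data and with limma's fry, which asks whether the genes of a list move, on balance, 1 way and does not compare them with other genes.

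Named genes are the row fam177a1 and, in each comparison, up to 10 genes with the highest and 10 with the lowest log2 fold change among called genes. These had a mean of at least 1 CPM over the 6 libraries compared, no overlap between the genotypes and a gene symbol. For each list called or described, up to 4 members with the smallest adjusted p were named as well. The part of the rule on called neighbours of the targeted genes was not applied, because positions on the build of the counts were not at hand. Genes named outside this rule are marked where they appear.

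The correlation of the mutants' log2 fold changes across genes was set against 20 simulated pairs of unchanged mutants that shared the same wild-type libraries. Calls by chromosome were compared with Fisher's exact test, two-sided, adjusted over 25 chromosomes, for the 18328 tested genes that the reference places. This is a departure from the plan. The plan allowed the chromosome test only with positions on the build of the counts, and it was run with the grouping by chromosome of the other assembly, a decision made after the data were seen. The planned test for the chromosome of fam177a1b was not run, since that gene could not be matched.

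The fits were tested on simulated data drawn from the real means and library sizes for all 21694 genes, with 100 genes changed by 2-fold and 100 by 4-fold. In addition, 2 gene lists and further genes on the chromosome carrying fam177a1 were changed. Of the genes changed by 2-fold, 87% were called in the right direction for single mutant against wild type, 85% for double mutant against wild type and 78% for double against single mutant. Of those changed by 4-fold, 95%, 95% and 97% were. Unchanged genes made up 9.81%, 6.58% and 5.05% of all calls in the same order, each above the nominal level, the last barely. Each share rests on 1 simulated data set, so the shares do not rank the comparisons. Camera called the 2 planted lists in each comparison and none of the others. The simulated genes were drawn independently of each other, so this does not test the preset correlation on which the list calls rest. In the comparison of double with single mutants, 1 chromosome other than that of fam177a1 was also called. Changed genes were not confined to the chromosome carrying fam177a1, and whether that call is false was not examined.

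The alternatives were other scalings, other filters on low counts, DESeq2's Wald test, limma-voom, a fit without robust estimation, only the 6 libraries compared, the replicate number as a block, stricter thresholds and leaving out each of the 9 libraries in turn. A further 2 were chosen after seeing the data: the single mutant reduced to its first library, and the rows of 14 non-coding RNA names left out. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. DESeq2 gave no adjusted p for 2 genes in each comparison.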

Results

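RNA was measured in 9 libraries of pooled whole larvae at 8 days post fertilization, 3 from wild type, 3 from single mutants lacking fam177a1a and 3 from double mutants lacking fam177a1a and fam177a1b. FAM177A1, the human counterpart, encodes a protein of the Golgi complex. Per library, 21.4 M counts were assigned to genes on average in wild type, 17.6 M in single mutants and 18.1 M in double mutants. At these depths, 3 counts in 1 library correspond to between 0.121 and 0.177 CPM.

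The row named fam177a1 was low in every mutant library. It had 669, 490 and 487 counts in the wild-type libraries, 8, 14 and 11 in the single mutants and 15, 9 and 8 in the double mutants. In CPM these were 25.1 ± 2.45, 0.638 ± 0.186 and 0.603 ± 0.252 (SD, n = 3 each). The log2 fold change was −5.29 (SE 0.21, edgeR adjusted p = 2.70e-10) in single mutants and −5.39 (SE 0.21, adjusted p = 1.84e-10) in double mutants. Between the mutants it was −0.10 (adjusted p = 0.920). The row sets the mutants apart from wild type. Its counts overlap between the 2 mutant genotypes, and fam177a1b could not be matched to a row of its own. The single mutants' label names no fam177a1b allele, and any part of the row from fam177a1b was at most 0.638 CPM there on average.

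**Figure D1:**
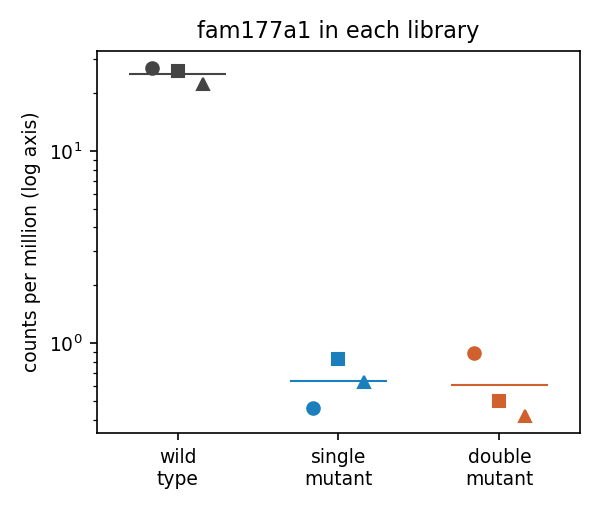
CPM of the row named fam177a1 on a log axis, with 1 point per library (circle, square and triangle for replicates 1, 2 and 3) and a line at the mean of each genotype. The wild-type libraries lie at 22.4 CPM or more and the mutant libraries at 0.890 CPM or less.

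Wild-type and mutant libraries were apart on the first principal component of log2 CPM, which held 55.4% of the variance. The second held 16.5%. On it, single-mutant replicates 2 and 3 lay at 34.1 and 38.0, the double mutants between −31.5 and −25.8, and single-mutant replicate 1 at −1.98. That library also stood alone on the third component, at −39.4. Its correlations with the double mutants were 0.983, 0.979 and 0.983, and with the other single mutants 0.978 and 0.977. The share of counts on Metazoa_SRP, the RNA of the signal recognition particle, was 4.603%, 4.796% and 3.83% in wild type, 5.41%, 5.06% and 4.79% in single mutants and 6.98%, 5.98% and 6.19% in double mutants.

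**Figure D2:**
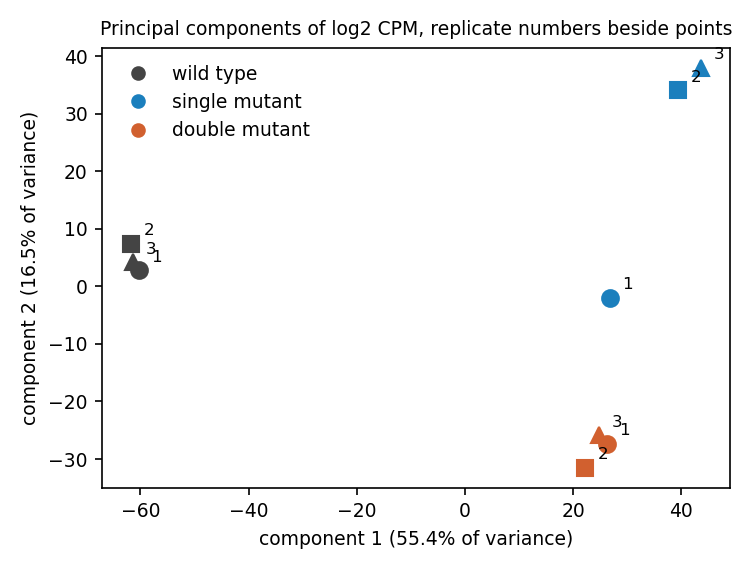
Scores of the 9 libraries on the first principal component (horizontal, 55.4% of the variance) and the second (vertical, 16.5%) of log2 CPM, coloured by genotype with the replicate number beside each point. Single-mutant replicate 1 lies between the other single mutants and the double mutants on the second component.

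The comparison of single mutants with wild type asked what differs in larvae without fam177a1a. Genes of cholesterol synthesis and of DNA replication and cell division fell, while clock, interferon-stimulated, inflammatory, immediate early and fasting-response genes rose. These are calls by camera with its preset correlation, and with an estimated correlation none of the 7 lists passed (adjusted p from 0.251 to 0.668). The mRNA of sqlea, squalene epoxidase of the sterol pathway, fell from 148 ± 16.2 to 24.5 ± 4.34 CPM (SD, n = 3 each, log2 fold change −2.59, SE 0.12, edgeR adjusted p = 3.22e-09). Antiviral mxb, a dynamin-like GTPase induced by interferon, rose from 0.450 ± 0.133 to 12.3 ± 6.84 CPM (log2 fold change 4.77, SE 0.54, adjusted p = 0.000178). The enzyme gck, glucokinase, which traps glucose in hepatocytes after feeding, fell from 14.4 ± 4.87 to 0.481 ± 0.228 CPM (log2 fold change −4.89, SE 0.35, adjusted p = 7.40e-07).

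Of 32 measured genes of cholesterol synthesis and SREBP2 regulation, 25 fell and 3 rose over all genes tested, and 26 and 3 adjusted over the list alone. The list was called by camera (adjusted p = 5.58e-13; adjusted p = 0.251 with an estimated correlation). Among those that fell were msmo1, a methylsterol monooxygenase, from 256 ± 31.0 to 65.0 ± 5.22 CPM, and idi1, an isomerase of the mevalonate pathway, from 179.6 ± 10.15 to 64.3 ± 4.11 CPM. Among the 3 that rose were ldlra, the LDL receptor (log2 fold change 0.93), and insig1, which retains the SREBP activator in the endoplasmic reticulum (0.61, adjusted p = 0.0413), named after their values were seen. The call of insig1 was lost without wild-type replicate 1 (adjusted p = 0.0902) or 3 (0.0775), single-mutant replicate 2 (0.107) or 3 (0.0737) or double-mutant replicate 2 (0.0510), with limma-voom (0.0587), with no filter on low counts (0.0578), with only the 6 libraries compared (0.06998) and, in an alternative chosen after seeing the data, with the single mutant reduced to its first library (0.581). In each library of the single mutants the median of the list lay between −1.58 and −1.41 log2 units from the wild-type mean.

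In the list of DNA replication and cell division, 79 of 88 genes fell and none rose, and 84 fell adjusted over the list alone (camera adjusted p = 3.85e-23; adjusted p = 0.577 with an estimated correlation). lig1, the DNA ligase that joins Okazaki fragments, went from 40.8 ± 1.89 to 13.2 ± 1.65 CPM, and ndc80, a kinetochore protein, from 26.1 ± 1.25 to 12.4 ± 1.38 CPM. The list's median was −0.55 in single-mutant replicate 1 against −0.90 and −0.92 in replicates 2 and 3. Mitochondrial ribosomal proteins fell in 53 of 74 genes, 59 adjusted over the list alone (adjusted p = 7.20e-12; 0.639 with an estimated correlation, also an adjusted p). Heat shock and cytosolic chaperone genes fell in 31 of 42, with 2 higher, and in 31 with 3 higher adjusted over the list alone (adjusted p = 1.13e-07; adjusted p = 0.577 with an estimated correlation). hspa4a, a nucleotide exchange factor of Hsp70, fell from 159 ± 7.14 to 68.1 ± 13.1 CPM, whereas hsf2, a heat shock transcription factor, rose from 21.7 ± 2.42 to 71.4 ± 4.78 CPM.

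Of 52 circadian clock genes, 35 rose and 8 fell (36 and 8 adjusted over the list alone, adjusted p = 1.35e-08; adjusted p = 0.668 with an estimated correlation). nr1d1, a repressor of the clock loop, rose from 17.5 ± 1.85 to 96.9 ± 11.7 CPM, and dbpb, a PAR-bZIP output factor, from 19.1 ± 0.641 to 89.1 ± 16.4 CPM. The list's median was 0.37 in single-mutant replicate 1 and 0.84 and 1.01 in the other replicates. Of 40 genes of gluconeogenesis, fasting and atrophy, 24 rose and 2 fell (25 and 3 adjusted over the list alone, adjusted p = 1.55e-06; adjusted p = 0.577 with an estimated correlation), with medians of 0.47, 0.78 and 1.08 in replicates 1, 2 and 3. fbxo32, a ubiquitin ligase of muscle atrophy, was at 1.83 ± 0.726 CPM in wild type, at 58.1 and 66.6 CPM in single-mutant replicates 2 and 3 and at 10.5 CPM in replicate 1 (edgeR adjusted p = 0.00461, limma-voom adjusted p = 0.0565). Of 33 glucocorticoid-response genes, 15 rose and 1 fell (16 and 2 adjusted over the list alone, adjusted p = 0.000515; adjusted p = 0.639 with an estimated correlation). The medians of that list were 0.17, 0.46 and 0.77 in replicates 1, 2 and 3, and 0.13 to 0.20 in the double mutants.

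Interferon-stimulated genes rose in 29 of 38, with none lower, and in 30 adjusted over the list alone (adjusted p = 3.26e-09; adjusted p = 0.639 with an estimated correlation). The ubiquitin-like modifier isg15 had 38.2, 8.47 and 29.5 CPM in the single mutants and 1.63 ± 0.756 CPM in wild type, and mxe rose from 1.16 ± 0.336 to 11.8 ± 4.52 CPM. cgas, the cytosolic DNA sensor, rose from 1.54 ± 0.490 to 27.7 ± 10.34 CPM. Inflammatory and acute-phase genes rose in 32 of 55 and fell in 3 (36 and 3 adjusted over the list alone, adjusted p = 1.05e-08; adjusted p = 0.577 with an estimated correlation). Complement component c3a.3 rose from 65.5 ± 7.34 to 166 ± 21.6 CPM. Of 42 immediate early genes, 24 rose and 1 fell (25 and 2 adjusted over the list alone, adjusted p = 3.49e-07; adjusted p = 0.639 with an estimated correlation), with a median of 0.28 in replicate 2 against 1.29 and 1.13 in replicates 1 and 3. p53 targets and apoptosis genes rose in 27 of 48 and fell in 2 (28 and 3 adjusted over the list alone, adjusted p = 2.70e-08; adjusted p = 0.577 with an estimated correlation). diabloa, a releaser of caspases from inhibition, rose from 17.9 ± 2.13 to 121 ± 15.0 CPM.

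Further lists rose in single mutants. They were liver proteins (38 of 69 higher and 9 lower, adjusted p = 4.10e-05; adjusted p = 0.668 with an estimated correlation), skeletal muscle (41 of 102 higher and 9 lower, adjusted p = 1.73e-05; 0.668) and neuronal and synaptic genes (30 of 113 higher and 6 lower, adjusted p = 0.00114; 0.677). Lysosome and autophagy genes (28 of 80 higher and 6 lower, adjusted p = 0.00532; 0.677) and mitochondrially encoded genes (7 of 13 higher and 1 lower, adjusted p = 0.0136; 0.677) rose as well, the last number in each bracket being the adjusted p with an estimated correlation. Adjusted over the list alone, the counts higher and lower were 40 and 10, 41 and 9, 29 and 5, 28 and 6, and 8 and 1 in this order. Ionocyte genes rose (6 of 29 higher and 2 lower, 6 and 1 adjusted over the list alone, adjusted p = 0.0296; 0.677 likewise), a call lost without single-mutant replicate 2 (adjusted p = 0.0508) or 3 (0.119). Over all genes, 4222 of 21694 were higher and 4894 lower, so the share of ionocyte genes called higher is near that of all genes. Nuclear genes of the respiratory chain fell in 28 of 86 and rose in 3 (26 and 2 adjusted over the list alone, adjusted p = 0.00394; adjusted p = 0.762 with an estimated correlation), a call lost without wild-type replicate 1 (adjusted p = 0.366) or single-mutant replicate 2 (0.0835). Proteasome genes had 14 of 43 lower and 4 higher (15 and 4 adjusted over the list alone, adjusted p = 0.0394; adjusted p = 0.762 with an estimated correlation). Their median was −0.14 and their mean 0.14, and the call ended without wild-type replicate 1 (adjusted p = 0.298), single-mutant replicate 2 (0.271) or double-mutant replicate 1 (0.0740), 2 (0.0810) or 3 (0.0847). It also ended with DESeq2 size factors (0.0528) and with a stricter filter on low counts (0.0780). Of the lists in this paragraph, fry did not call neuronal (adjusted p = 0.0783), respiratory chain (0.0991) and proteasome genes (0.0781).

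Genes of the Golgi itself moved in both directions. Of 80 genes for Golgi structure, tethers and coats, 13 rose and 27 fell (15 and 28 adjusted over the list alone), and the list was called neither by camera (adjusted p = 0.371) nor by fry (0.0551). acbd3, a Golgi scaffold protein, fell by 0.75 on the log2 scale, while arfgap1, which drives release of the COPI coat, rose by 0.70. Camera also did not call the lists for exit from the endoplasmic reticulum (adjusted p = 0.204) and glycan synthesis (0.376), which fry called as lower (adjusted p = 0.0346 and 0.0189). The lists for the unfolded protein response (camera adjusted p = 0.292), myelin and glia (0.267) and hair cells (0.909) were called by neither tool. Within the unfolded protein response nupr1b, a stress-induced chromatin regulator, rose by 2.53 and ddit3, the transcription factor CHOP, by 0.74, while ficd, which modifies the chaperone BiP, fell by 0.97 on the log2 scale.

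Over all genes, edgeR called 9116 of 21694, of which 4222 were higher and 4894 lower in single mutants. With TMM factors computed without the most abundant tissue lists, 4664 of 9049 were higher, so which direction held more genes changed with the scaling. At least a 2-fold change was found in 1977, of which more were higher (1139) than lower (838). The lowest folds also held ftr52p, without a count in the single mutants and at least 43.7-fold lower, and hadhab, a subunit of the mitochondrial trifunctional protein, from 134 ± 8.56 to 8.68 ± 0.482 CPM. The small nuclear RNAs named U4 (30.3 ± 13.7 to 1.33 ± 0.146 CPM) and U2 (146 ± 43.3 to 9.14 ± 0.460 CPM), each summed over copies that share a name, were among them. Both lost their call when the single mutant was reduced to its first library (adjusted p = 0.108 and 0.0543), an alternative chosen after seeing the data. Camera called 19 of 46 lists and fry 24. With an estimated correlation limma's camera called 0 (smallest adjusted p 0.251).

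**Figure D3:**
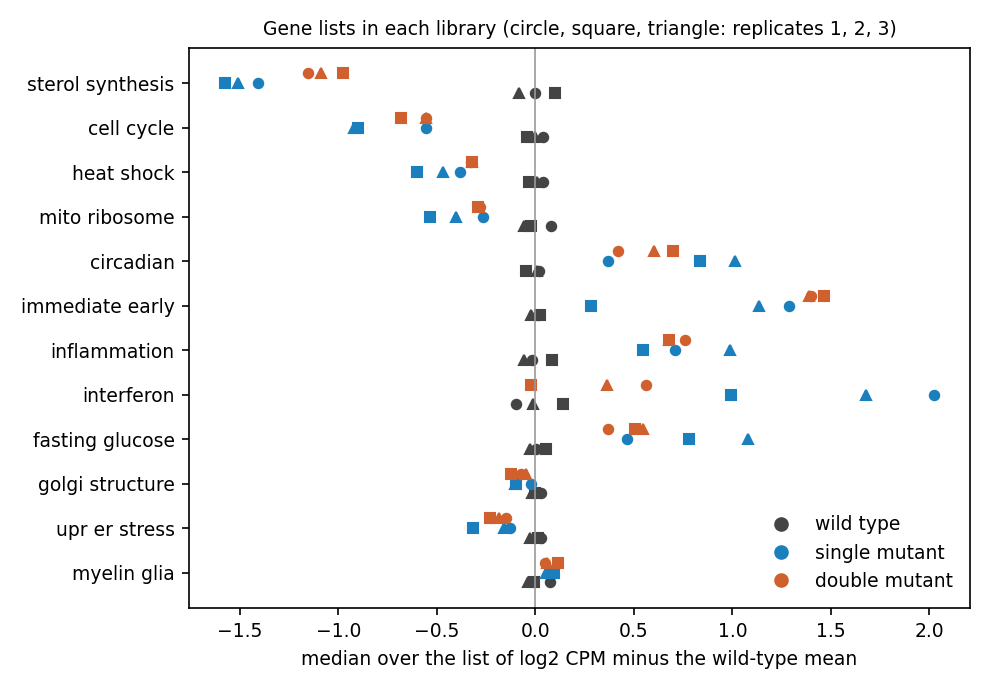
Median over each gene list of log2 CPM minus the wild-type mean (horizontal), with 1 point per library, coloured by genotype and shaped by replicate. The mutant libraries lie between −1.58 and −0.98 for sterol synthesis, and all 9 libraries between −0.12 and 0.03 for the Golgi list.

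The comparison of double mutants with wild type asked what differs in larvae without either gene. The groups that moved were largely those of the single mutants, with immediate early and inflammatory genes higher and sterol and cell division genes lower. These are calls by camera with its preset correlation, and with an estimated correlation none of the 4 lists passed (adjusted p from 0.174 to 0.514). fosl1a, a subunit of the AP-1 transcription factor, rose from 6.22 ± 0.202 to 103 ± 12.6 CPM (SD, n = 3 each, log2 fold change 4.04, SE 0.68, edgeR adjusted p = 0.00555). The haem-binding plasma protein hemopexin, hpxa, rose from 5.35 ± 1.80 to 82.0 ± 24.1 CPM (log2 fold change 3.93, SE 0.42, adjusted p = 0.000683). apip, an enzyme of methionine salvage, fell from 14.5 ± 2.39 to 0.0558 ± 0.00353 CPM (adjusted p = 4.73e-10), a ratio of 258 with a 95% counting interval of 88.0 to 1253. gck fell as in the single mutants, to 0.553 ± 0.202 CPM.

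Sterol synthesis genes fell in 26 of 32 and rose in 1 (27 and 1 adjusted over the list alone, adjusted p = 3.67e-15; adjusted p = 0.174 with an estimated correlation). acat2, an acetyl-CoA acetyltransferase at the head of the pathway, went from 53.8 ± 2.496 to 22.0 ± 0.955 CPM. Cell division genes fell in 66 of 88, with none higher (74 adjusted over the list alone, adjusted p = 4.33e-21; adjusted p = 0.514 with an estimated correlation), among them kif4, a chromosome-associated kinesin, with a log2 fold change of −0.91. Heat shock genes fell in 24 of 42 and rose in 3 (28 and 3 adjusted over the list alone, adjusted p = 8.32e-06; adjusted p = 0.514 with an estimated correlation). Mitochondrial ribosomal proteins fell in 33 of 74 and rose in 1 (43 and 1 adjusted over the list alone, adjusted p = 4.46e-08; adjusted p = 0.636 with an estimated correlation). Haemoglobin and erythrocyte genes had 15 of 30 lower and 5 higher in both adjustments (adjusted p = 0.0232, adjusted p = 0.636 with an estimated correlation), a call lost without wild-type replicate 1 (adjusted p = 0.101). The embryonic globin hbbe1.2 fell from 536 ± 73.7 to 71.6 ± 0.126 CPM. Nrf2 targets and oxidative stress genes fell in 19 of 46 and rose in 3 (20 and 4 adjusted over the list alone, adjusted p = 0.00588; adjusted p = 0.563 with an estimated correlation). keap1b, a sensor that holds Nrf2 inactive, fell from 37.5 ± 3.23 to 12.2 ± 0.873 CPM.

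Immediate early genes rose in 28 of 42, with none lower (33 adjusted over the list alone, adjusted p = 2.44e-16; adjusted p = 0.514 with an estimated correlation), and nr4a3, an orphan nuclear receptor, went from 14.7 ± 1.98 to 48.6 ± 3.60 CPM. Inflammatory genes rose in 30 of 55 and fell in 4 (34 and 4 adjusted over the list alone, adjusted p = 5.22e-09; adjusted p = 0.514 with an estimated correlation), and f3a, tissue factor, went from 5.18 ± 0.476 to 15.9 ± 1.83 CPM. Clock genes rose in 26 of 52 and fell in 11 (29 and 11 adjusted over the list alone, adjusted p = 1.24e-06; adjusted p = 0.636 with an estimated correlation), and nr1d1 reached 127 ± 2.96 CPM. p53 and apoptosis genes rose in 23 of 48 and fell in 2 (24 and 2 adjusted over the list alone, adjusted p = 6.96e-06; adjusted p = 0.514 with an estimated correlation). Fasting genes rose in 17 of 40 and fell in 2, in both adjustments (adjusted p = 5.75e-05; adjusted p = 0.537 with an estimated correlation). Interferon-stimulated genes had 7 of 38 higher and 2 lower, in both adjustments, and were not called (adjusted p = 0.0952). Of these, psmb9a, an immunoproteasome subunit, rose from 0.122 ± 0.212 to 2.54 ± 0.7305 CPM. Its wild-type mean lay near the level of 3 counts in 1 library. Among the highest folds were also psmb13a and psmb12, whose calls held in 8 and 4 of the 9 fits without 1 library. For these genes, as for every gene compared with wild type, separate stocks cannot be told apart from genotype.

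Liver proteins (35 of 69 higher and 9 lower, adjusted p = 8.24e-06; adjusted p = 0.539 with an estimated correlation) and muscle precursor genes (6 of 22 higher, adjusted p = 0.00676; 0.514) rose. So did skeletal muscle (34 of 102 higher and 11 lower, adjusted p = 0.00132; 0.636), neuronal genes (20 of 113 higher and 4 lower, adjusted p = 0.00106; 0.684), glucocorticoid-response genes (12 of 33 higher and 1 lower, adjusted p = 0.00390; 0.604) and mitochondrially encoded genes (6 of 13 higher and 1 lower, adjusted p = 0.0175; 0.636), the last number again being the adjusted p with an estimated correlation. Adjusted over the list alone, the counts higher and lower were 35 and 11, 6 and 0, 36 and 11, 17 and 3, 14 and 1, and 8 and 1 in this order. Exocrine pancreas genes rose (12 of 32 higher and 2 lower in both adjustments, adjusted p = 0.0206; adjusted p = 0.636 with an estimated correlation), a call lost without wild-type replicate 3 (adjusted p = 0.0830). Proteasome genes fell in 22 of 43 and rose in 4 (28 and 5 adjusted over the list alone, adjusted p = 0.000197; adjusted p = 0.636 with an estimated correlation), with a median of −0.23 and a mean of 0.16. Respiratory chain genes fell in 25 of 86 and rose in 1 (22 and 1 adjusted over the list alone, adjusted p = 0.00359; adjusted p = 0.836 with an estimated correlation), a call lost without wild-type replicate 1 (adjusted p = 0.343). The Golgi list had 7 of 80 higher and 17 lower in both adjustments and was not called by camera (adjusted p = 0.200), while fry called it as lower (adjusted p = 0.0305). Of the lists camera called, fry did not call skeletal muscle (adjusted p = 0.0771), neuronal (0.136) and respiratory chain genes (0.147). Within the Golgi list, cog6, a subunit of the COG tethering complex, fell by 0.76 and stx5a, a Golgi SNARE, by 0.59 on the log2 scale.

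edgeR called 6990 of 21694 genes, 3084 higher and 3906 lower in double mutants, and 1407 by at least 2-fold. Among these 1407 more genes were higher (808) than lower (599). With upper-quartile scaling, 3404 of all called genes were higher and 3533 lower. acot15 had no count in the double mutants and was at least 241-fold lower. Camera called 20 of 46 lists, fry 22, and limma's camera with an estimated correlation 0 (smallest adjusted p 0.174).

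The comparison of double with single mutants asked what the added loss of fam177a1b goes with, and it tests the difference between the mutants directly. Interferon-stimulated genes fell in double mutants relative to single mutants and sterol synthesis genes rose. Both are calls by camera with its preset correlation, lost with an estimated correlation (adjusted p = 0.564 and 0.491), and fry called the sterol list (adjusted p = 0.0313) and not the interferon list (0.111). The signal transducer stat2, which carries the interferon signal to the nucleus, fell from 71.8 ± 10.8 to 33.9 ± 4.08 CPM (SD, n = 3 each, log2 fold change −1.08, SE 0.13, edgeR adjusted p = 0.000974). sqlea rose from 24.5 ± 4.34 to 53.7 ± 2.34 CPM (log2 fold change 1.13, SE 0.12, adjusted p = 0.000139). Some single genes differed by more: cyp2p9, a cytochrome P450, rose from 1.77 ± 0.464 to 20.1 ± 2.21 CPM (log2 fold change 3.50, SE 0.17, adjusted p = 7.97e-09), near its 18.8 ± 1.24 CPM in wild type.

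Of 38 interferon-stimulated genes, 13 fell and none rose (23 lower and 1 higher adjusted over the list alone, adjusted p = 6.04e-14; adjusted p = 0.564 with an estimated correlation). trim25, a ubiquitin ligase of antiviral signalling, fell by 0.93, mxa by 2.05 and mxe by 2.73 on the log2 scale. The list's median was 2.02, 0.99 and 1.68 in single-mutant replicates 1, 2 and 3 and 0.56, −0.02 and 0.36 in the double mutants. Of 32 sterol synthesis genes, 9 rose and 1 fell (18 and 2 adjusted over the list alone, adjusted p = 1.01e-09; adjusted p = 0.491 with an estimated correlation). This was the only list of the 46 called by fry (adjusted p = 0.0313).

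Fewer single genes passed in the other lists. Heat shock genes rose in 6 of 42 (9 adjusted over the list alone, adjusted p = 0.000384; adjusted p = 0.564 with an estimated correlation). Immediate early genes (adjusted p = 4.63e-07; adjusted p = 0.601 with an estimated correlation), cell division genes (2.19e-06; 0.795) and mitochondrial ribosomal proteins (7.41e-06; 0.795) rose as lists, with 1 of 42, 1 of 88 and 0 of 74 genes higher and 2, 1 and 0 adjusted over the list alone. The immediate early list's median was 0.28 in single-mutant replicate 2 against 1.29 and 1.13 in replicates 1 and 3. In double mutants it was 1.39 to 1.46. Mitochondrial ribosomal proteins with 0 called genes had a median log2 fold change of 0.13. For both cell division and mitochondrial ribosome genes, single-mutant replicate 1 lay at the level of the double mutants (medians −0.55 against −0.68 to −0.55, and −0.27 against −0.29 to −0.28). With that library as the only single mutant, an alternative chosen after seeing the data, cell division genes fell (adjusted p = 0.0255) and mitochondrial ribosomal proteins (0.737), heat shock (0.0782), immediate early (0.132), p53 (0.627), lipid metabolism (0.753) and keratin genes (0.527) were not called. Lysosome genes fell, with 4 of 80 lower (11 adjusted over the list alone, adjusted p = 2.48e-05; adjusted p = 0.564 with an estimated correlation), among them sqstm1, the autophagy receptor p62, from 19.2 ± 5.51 to 10.15 ± 0.786 CPM. That gene lost its call without single-mutant replicate 2 (adjusted p = 0.0930) or 3 (0.0818) or without double-mutant replicate 1 (0.0642), 2 (0.117) or 3 (0.118). p53 genes (adjusted p = 0.000710; adjusted p = 0.615 with an estimated correlation), lipid metabolism genes (0.00120; 0.600) and epidermal keratin genes (0.00475; 0.564) fell as lists, with 1 of 48, 1 of 64 and 3 of 57 genes lower. Adjusted over the list alone, 8 were lower and 3 higher, 7 lower and none higher, and 7 lower and 1 higher in this order. The keratin list's median was −0.06 in single-mutant replicate 1 against 0.34 and 0.40 in replicates 2 and 3.

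The remaining list calls were lost without 1 or more single libraries. Clock genes fell (adjusted p = 0.00214; adjusted p = 0.845 with an estimated correlation) with 1 of 52 higher and none lower in both adjustments, a call lost without single-mutant replicate 2 (adjusted p = 0.0974) or 3 (0.0989). Fasting genes fell (0.00265; 0.680) with 0 of 40 called in either adjustment, a call lost without replicate 3 (0.0989), and skeletal muscle fell (0.00265; 0.795) with 1 of 102 higher and 2 lower (2 and 8 adjusted over the list alone), lost without the same library (0.0507). Exocrine pancreas genes rose (0.0103; 0.680) with 2 of 32 higher in both adjustments, lost without single-mutant replicate 2 (0.0521) or double-mutant replicate 3 (0.0522). Enterocyte genes rose (0.0213; 0.564) with 6 of 59 higher and 1 lower (9 and 1 adjusted over the list alone), lost without single-mutant replicate 1 (0.162) or 2 (0.0681) or double-mutant replicate 1 (0.0659). Ionocyte genes fell (0.0227; 0.795) with 0 of 29 called in either adjustment, lost without single-mutant replicate 2 (0.0521) or 3 (0.247) or double-mutant replicate 3 (0.124). Each second number in brackets is the adjusted p with an estimated correlation. With the single mutant reduced to its first library, the alternative chosen after seeing the data, clock genes rose instead (adjusted p = 3.14e-07), fasting (0.132) and ionocyte genes (0.525) turned direction and were not called, and skeletal muscle was not called (0.773). The single-mutant replicate 1 was nearest to the double mutants in several of these groups. Its fbxo32 level was 10.5 CPM, where the double mutants had 8.72 to 10.4 CPM, and its fkbp5 level, of a glucocorticoid-induced cochaperone named after its values were seen, was 80.3 CPM against 546 and 586 CPM in replicates 2 and 3.

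edgeR called 362 of 21694 genes, 145 higher and 217 lower in double mutants, and 124 by at least 2-fold. An unadjusted p under 0.05 was found for 3894. The number depended on single-mutant replicate 1: without it 3860 genes were called, without replicates 2 or 3 it was 213 or 159, and without double-mutant replicates 1, 2 or 3 it was 219, 108 or 142. DESeq2 called 883 and a fit of only the 6 libraries 184. The Golgi list was called between the mutants neither by camera (adjusted p = 0.588) nor by fry (0.710). Camera called 16 of 46 lists and fry 1, and with an estimated correlation limma's camera called 0 (smallest adjusted p 0.491).

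**Figure D4:**
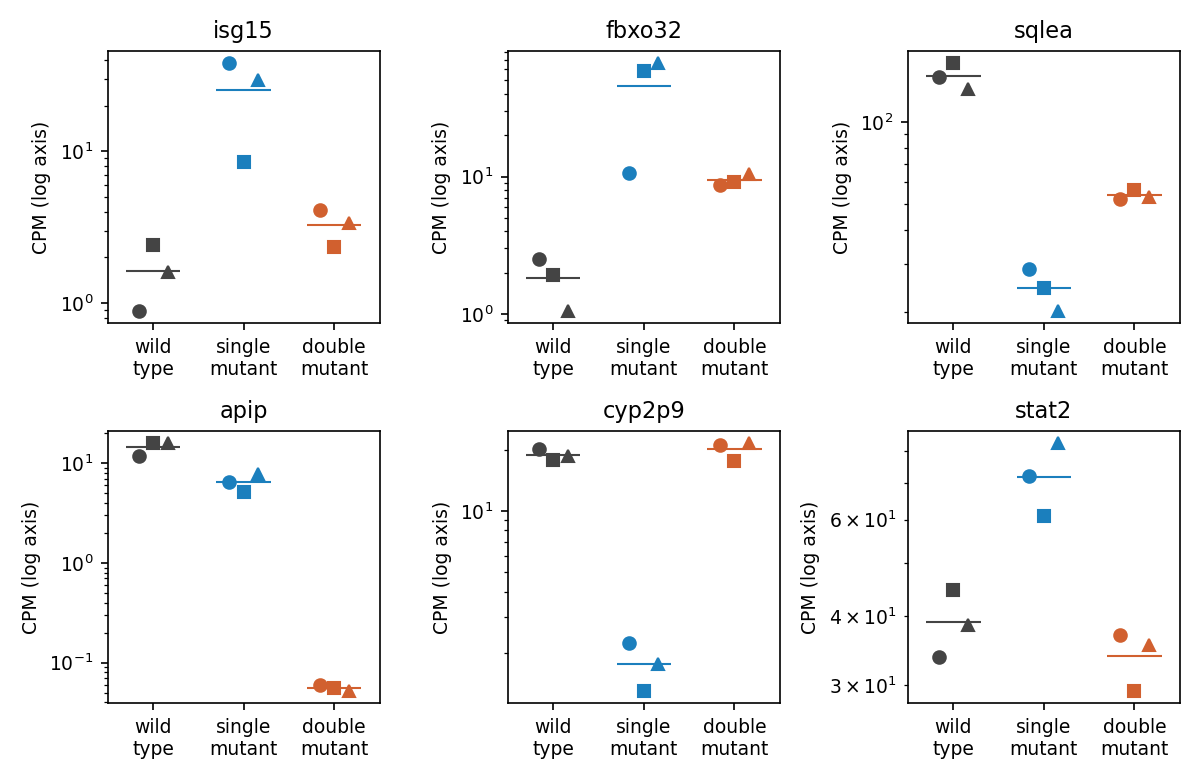
CPM of 6 genes on log axes, with 1 point per library, shaped by replicate, and a line at the mean of each genotype. For apip and cyp2p9, single-mutant replicate 1 lies with the other single mutants, and for fbxo32 it lies at 10.5 CPM beside the double mutants.

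The fold changes of the mutants against wild type were alike across genes. Pearson's correlation over the 21694 genes was 0.839 and Spearman's 0.821. The mutants share the wild-type libraries, which alone gave 0.478 and 0.451 in 20 simulated pairs of unchanged mutants, and genes are not independent replicates. The covariance was 0.460 against 0.0227 in the simulations, a difference of 0.437. Called in both mutants were 2464 genes that rose in each and 3319 that fell in each, where the simulations gave 0.05 and 0.1 on average. Independent calls would give 600 and 881, a value that leaves out the shared wild-type libraries, so the excess over either is not a measure of a shared effect. Opposite calls were made for 16 genes, among them mxa, gpx3 and adgrf7, named after their values were seen. For mxa the call in double mutants was lost without wild-type replicate 1 (adjusted p = 0.0546) or double-mutant replicate 1 (0.0933) or 3 (0.05496), and for adgrf7 the call in single mutants was lost with the single mutant reduced to its first library (0.354), an alternative chosen after seeing the data. Without the genes called in either comparison the correlation was 0.561.

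**Figure D5:**
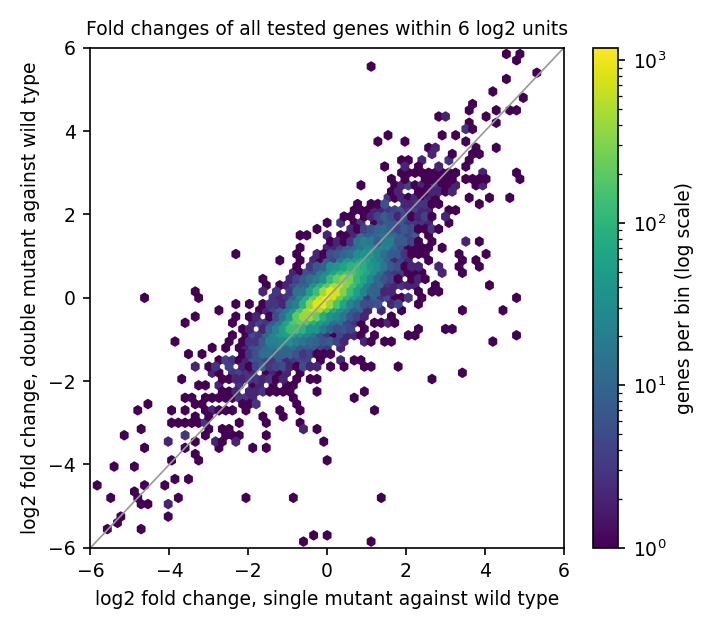
Log2 fold change of each tested gene in single mutants (horizontal) and double mutants (vertical) against wild type, as the number of genes per bin on a log colour scale, for genes within 6 log2 units. Most genes lie near the diagonal line of equal change, with a Pearson correlation of 0.839 over all genes.

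Where called genes lay was compared by chromosome. Genes on the chromosome carrying fam177a1 were called no more often than others in single mutants against wild type (odds ratio 1.01, Fisher's exact adjusted p = 1) or in double mutants against wild type (odds ratio 1.13, adjusted p = 0.646). Between the mutants, 4 of 25 chromosomes passed, 2 with more calls than the rest and 2 with fewer. The highest odds ratio was 3.78 (adjusted p = 1.91e-10). The highest ratio over the chromosomes was 1.44 without single-mutant replicate 1 and 8.45 without double-mutant replicate 2, and 1 to 3 chromosomes passed when 1 library was left out. The chromosome carrying fam177a1 was among those with fewer: 2 of 696 genes were called (0.287%, against 1.77% elsewhere, adjusted p = 0.00791), a call lost with DESeq2 (adjusted p = 0.165) and when any 1 of the 8 libraries other than wild-type replicate 1 was left out (adjusted p from 0.0568 to 0.488). The names used here do not place fam177a1b on a chromosome.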

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

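The list tests between the mutants with their refits and the counts of other groupings of the libraries were planned, the test of the chromosome carrying fam177a1 was planned for positions on the assembly of the counts and was run, by a decision made after the data were seen, with the chromosomes of another, and the tests of gene length, time of day, stocks, sequencing depth, mislabelling, mixed larvae, the neighbours of fam177a1 and the single mutant reduced to its first library were chosen only after the result was seen.

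Of the 46 gene lists, 4 stood out because the double mutants' change differed from the single mutants' change in the direct test between them, while only 1 of the mutants passed against wild type. Interferon-stimulated genes rose in single mutants and were lower in double than in single mutants (camera adjusted p = 6.04e-14, median log2 fold change −0.69 between the mutants). Lysosome and autophagy genes had the same pattern (2.48e-05, median −0.10), as did ionocyte genes (0.0227, median −0.13). Exocrine pancreas genes rose in double mutants and were higher there than in single mutants (0.0103, median 0.08). With a correlation estimated from the data none of the 4 passed (adjusted p = 0.564, 0.564, 0.795 and 0.680 in this order). The ionocyte call was also lost without single-mutant replicate 2 (0.0521) or 3 (0.247) or double-mutant replicate 3 (0.124), and it turned direction with the single mutant reduced to its first library (0.525). The pancreas call was lost without single-mutant replicate 2 (0.0521) or double-mutant replicate 3 (0.0522). The interferon list's median lay at 2.02, 0.99 and 1.68 in the single mutants and at 0.56, −0.02 and 0.36 in the double mutants, so the lowest single mutant was above the highest double mutant. The libraries overlapped in the other 3 lists: the lysosome median was 0.09 in the lowest single mutant and 0.10 in the highest double mutant, the ionocyte median 0.04 and 0.13, and the pancreas median 0.05 in the lowest double mutant and 0.08 in the highest single mutant.

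The 1st pattern weighed is that both mutants differ from wild type in clock, fasting, immediate early, cell division and sterol genes. A trend with gene length in the library preparation was argued against as the whole cause: of the 16 lists called the same way in both mutants, 15 stayed called once that trend was removed (proteasome genes did not), which moved genes by a median of 0.02 and at most 0.75 log2 units in the mutant libraries. Only the trend with the deposited gene length was tested, and other differences in library preparation were not. Collection at another time of day stays open. If the larvae stood at different phases of the clock, direct targets of the clock's activators and the activators themselves would move apart, and the smaller of the mutants' gaps between the medians of these groups was 1.58 log2 units. The 14 targets had medians of 1.23 in single and 1.12 in double mutants, and the 8 activators −0.35 and −0.65. A different clock phase at collection would give such a gap, but a change of the clock caused by the mutations would look the same. Whether the changes of fasting, cell division and sterol genes go with clock phase was not tested. Separate stocks or rearing cannot be told apart from genotype: 0 wild-type libraries are labelled as coming from the mutants' stock. A biological effect of losing fam177a1a stays among the open explanations, as untested.

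Strain variants linked to the mutated locus were tested over the whole chromosome carrying fam177a1, where the odds ratio for calls in single mutants against wild type was 1.01. This argues against an excess along the chromosome and does not bear on genes close to the locus. Of its 20 nearest tested neighbours on the other assembly, 12 were called in single mutants, against 42.0% of all genes, and 6 in double mutants, against 32.2%. Variants close to the locus stay open, as do variants linked to the second allele, since fam177a1b could not be matched. Between the mutants, another chromosome had 43 of 769 genes called (5.59%, against 1.54% elsewhere, odds ratio 3.78, Fisher's exact adjusted p = 1.91e-10). Variants linked to the second allele would give such an excess, but whether fam177a1b lies there is not known here. Without single-mutant replicate 1 the highest ratio over the chromosomes was 1.44 (Fisher's exact adjusted p = 0.000923). That fit called 3860 genes where the main fit called 362, so the ratios stand at unlike shares of called genes. Without any other single library the highest ratio lay between 3.59 and 8.45.

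The 2nd pattern is that single-mutant replicate 1 stands apart from replicates 2 and 3. Sequencing depth is argued against, since its total of 17.3 M counts lies between those of the other single mutants, 17.2 and 18.3 M. A mislabelled double mutant was tested with the 3852 genes called between the mutants when this library was left out that were also tested with all 9 libraries (3860 with those that were not). For 17.8% of them it lay nearer to the other single mutants than to the double mutants. The bound set for that test was 50%, and the value lay below it, which pointed towards mislabelling. A further test, chosen after that outcome, held out each double mutant in turn: replicate 1 was nearer to the single mutants for at least 16.6% of called genes, and a held-out double mutant for at most 8.69%. Both tests were first run on part of the genes as well, which is not reported here. This argues against a mislabelled double mutant like the 3 measured, although replicate 1 lay nearer to the double mutants for most genes in both tests. It cannot exclude a mislabelled double mutant of another clutch or hour, because each held-out library was compared with its own group. Larvae of another genotype in its pool of 7 were tested next. In CPM, replicate 1 lay at a median of 87.8% of the way from the other single mutants to the double mutants over the 3852 genes, and a share of double-mutant larvae would put every gene at about the same point. Of the 97 genes that differed by at least 4-fold, however, 38.1% lay under 1 of 7 of the way, against at most 2.06% for a held-out double mutant, which argues against double-mutant larvae as the whole cause. Wild-type larvae are argued against by the row fam177a1, at 0.458 CPM in replicate 1, where 1 of 7 of the lowest wild-type library would be 3.19 CPM. Clutch and hour of collection stay open, and no biological explanation was tested because the labels name none within a genotype.

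For each comparison, 1 of the 10 ways to divide its 6 libraries into 3 and 3, the real one, gave as many called genes: 9116, 6990 and 362, against at most 0 in the others by edgeR (up to 1911, 482 and 2836 genes at an unadjusted p under 0.05). Between the mutants, the 3 ways that put single-mutant replicate 1 with a pair of double mutants had 2674 to 2836 such genes and the other 6 at most 528. With 10 ways the share is never under 0.05. Each of the other ways put both genotypes into both groups, so the difference between genotypes entered the spread. The 0 calls there do not show how many genes would be called without such a difference.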

How the results depend on the processing

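The single mutant reduced to its first library and the leaving out of 14 non-coding RNA names were tests chosen only after seeing the data. Where no cause is given below, the cause was not tested.

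The row fam177a1 kept its direction and its call against wild type in every alternative run. Called genes numbered 8725 with DESeq2 and 9056 with limma-voom in single mutants against wild type, and 6697 and 7113 in double mutants. A 2-fold minimum left 1977, 1407 and 124 genes in the 3 comparisons, fewer by construction. An adjusted p under 0.01 left 4286 in double mutants against wild type and 104 between the mutants. Between the mutants DESeq2 called 883 and a fit of only the 6 libraries compared 184. With the replicate number as a block the counts were 9054, 7006 and 373. Leaving out 1 library in turn gave 7327 to 10363, 5230 to 8697 and 108 to 3860 genes, the last without double-mutant replicate 2 and without single-mutant replicate 1. With the single mutant reduced to its first library, 5485 genes were called against wild type and 177 against double mutants. The lone library is then assumed to vary like the others.

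The correlation of fold changes was 0.561 once genes called in either comparison were left out, which removes the largest changes, 0.796 with the single mutant reduced to its first library, and 0.8004 to 0.847 without each library. On the chromosome carrying fam177a1, the odds ratio for calls between the mutants lost its call with DESeq2 (0.565), at an adjusted p under 0.01 (0.308), with the first library alone (0.365) and in 8 of the 9 fits without 1 library, which ranged from 0 to 0.780.

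With a correlation estimated from the data, camera called 0, 0 and 0 lists in the 3 comparisons (smallest unadjusted p 0.00546, 0.00379 and 0.0107), and fry called 24, 22 and 1. Without each library camera called 16 to 23, 18 to 21 and 12 to 19. Cytosolic ribosomal proteins in single mutants had adjusted p from 0.00603 to 0.994 without each library, rising without wild-type replicate 1 and falling without wild-type replicate 3 (0.00883). With the first library alone, 9 lists turned direction between the mutants: circadian (adjusted p = 3.14e-07), glucocorticoid (0.000737), endothelial (0.00488) and neuronal (0.00673) rose, cell cycle (0.0255) and liver (0.0110) fell, and fasting (0.132), ionocyte (0.525) and mitochondrial ribosome genes (0.737) were not called. A further 74 sign changes concerned values past the threshold in neither setting.

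Of the values of genes named by the rule or in the text, fam177a1 aside, in the 9 fits without 1 library, 948 of 954 kept their side of the threshold in single mutants against wild type, 926 of 945 in double mutants, and 552 of 729 between the mutants. Most of these genes were picked from the same data for large folds or small adjusted p, so their shares do not stand for all called genes. Of all called genes, the fits without 1 library kept 7044 to 8594 of 9116 in single mutants against wild type. They kept 5085 to 6973 of 6990 in double mutants, and 104 to 361 of 362 between the mutants. At these depths 3 counts are 0.121 to 0.177 CPM. Folds are lower bounds where a genotype had no count, and ratios with counting intervals where it had 1 to 3.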

Other observations

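No further tests were made for this part, and its values were singled out only after they were seen.

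The small nuclear RNAs named U1, U2 and U4, each summed over copies that share a name, were higher in wild type than in either mutant, and U5 was not called (adjusted p = 0.428 and 0.455). The call of U4 in double mutants was lost without wild-type replicate 1 (adjusted p = 0.0510) or double-mutant replicate 1 (0.0567) or 2 (0.0666), with only the 6 libraries compared (0.0508), with the replicate number as a block (0.0580) and with the single mutant reduced to its first library (0.0538). U1 was at 53.2 ± 15.0 CPM in wild type, 4.37 ± 0.320 in single and 7.92 ± 2.19 in double mutants (SD, n = 3 each). U2 was at 146, 9.14 and 22.9 CPM in the same order, with 39.5 CPM in double-mutant replicate 3 against 15.0 and 14.1 CPM in the others. With 14 names of non-coding RNA left out, among them ribosomal RNA and Metazoa_SRP, 9040, 6944 and 366 genes were called.

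Embryonic globins went both ways. Against wild type, hbbe1.2 fell in single (log2 fold change −1.58, adjusted p = 1.20e-06) and double mutants (−2.90, 1.26e-08), and fell between them (−1.33, 9.71e-05). hbbe1.1 rose in single (1.66, adjusted p = 0.0213) and double mutants (2.08, 0.0121), the former call lost without wild-type replicate 3 (adjusted p = 0.0702), with only the 6 libraries compared (0.0665) and with the first library alone (0.109).

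The 2 class I MHC genes mhc1uba and mhc1uka had few counts in wild type. Whether this goes with genotype or with separate stocks cannot be told apart. mhc1uba had 0.0355 ± 0.0615 CPM in wild type, 3.85 ± 3.50 in single and 5.51 ± 1.72 in double mutants, and ratios from the summed counts of 124 (95% counting interval 33.9 to 1032) and 182 (49.9 to 1507). mhc1uka had such ratios of 57.5 (19.3 to 282) and 161 (54.6 to 783).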
